A study of Homo sapiens with 14 samples.

How the data were processed

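Poly(A)-selected, strand-specific RNA libraries of 14 MCF-10A samples were sequenced as paired reads on an Illumina NextSeq. The deposited table holds FPKM (fragments scaled by gene length and library size) for 34071 loci, 1 column per library. According to the submitters it was made with Bowtie, TopHat, Cufflinks and Cuffnorm on the hg19 genome. Tool versions, the annotation and the way libraries were scaled are not stated. All columns of values were matched to a sample by their names, and no pair of libraries had identical values. Of the loci 27543 have a gene name, 1204 of these carry the names of more than 1 gene, and 3732 share their name with another locus. The 6528 unnamed loci were left out of the gene tests. The table gives no positions and the annotation at hand is for another genome build, so it served only for gene names and their order along chromosomes, and no coordinates are printed.

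FPKM values carry no counts. They are scaled by gene length, so a short locus can reach a high value from few reads. Named short RNA loci held 31.75% to 76.25% of the FPKM sum of each library. The depth of each library relative to Hygro vector replicate 1 was estimated from the most frequent ratio between the values of loci below 0.5 FPKM in both libraries, and no counting interval can be given. MRTFB dN dPY replicate 1 is empty from a point on chromosome 7 onward: all 154 expressed genes of that chromosome up to PPIA have a value, and all 362 after it are at 0, as are all 380, 456 and 336 expressed genes of chromosomes 8, 9 and X. The 5235 loci of this part, 1554 of them named and at a median of 1 FPKM or more in the other 13 libraries, were treated as missing in this library. Other zeros were kept as values.

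Named loci with at least 1 FPKM in at least 2 libraries (13137) were tested on log2(FPKM + 1) with limma 3.58.1 (linear model on group, empirical Bayes with an intensity trend, two-sided) in R 4.3.3, all 14 libraries in 1 fit with 7 residual degrees of freedom (6 for loci missing in 1 library) and a prior of 3.77. P values were adjusted over genes by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The groups, tests, gene lists and the rule for naming genes were set before the data were examined. So were the comparisons, except MRTFB dN Y305A/dPY against MRTFB dN Y305A, which was not among those planned. The labels do not name the vector of each construct: the Hygro vector was used as control for YAP 5SA and the Puro vector for the MRTFB constructs. The replicate numbers were not used as a block.

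In the 27 fixed lists, which hold 542 genes, 536 were found in the table, 59 of them in loci with more than 1 gene. The 23 lists with at least 5 measured members were tested with camera on the moderated statistics with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals of each list. P values were adjusted over lists within a comparison. The lists for endothelial, fibroblast, neural and renal packaging line markers and for hosts of small noncoding RNA had too few measured members and were not tested. Genes are named by a fixed rule: the genes of MRTF, YAP, SRF and TEAD, the 5 largest changes in each direction among genes past the threshold at a mean of 3 FPKM or more whose replicates do not overlap, up to 4 passing members of each list, and a fixed set of YAP/TEAD and MRTF/SRF targets. Only some of the genes under this rule are given with values.

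Overlaps of called genes are given beside the number for independent calls and beside 50 simulated draws in which comparisons share only their control libraries. The classes of genes by mutant were compared with 50 draws in which the mutants equal MRTFB dN. The fit was tested on simulated data with 200 changed loci in each of 10 draws: in MRTFB dN against the Puro vector it called 8.3% of changes of 1 and 76.1% of changes of 2 on the log2 scale, with 4% false calls. In the data 4837 genes passed in this comparison. The adjusted threshold is less strict with so many calls, so these shares can be too low for it. Alternatives were a pseudocount of 0.1, no filter, scaling by the median of ratios, a fit on the compared groups only, no intensity trend, the replicate number as a block, the other vector as control, and leaving out each library in turn, which leaves 1 sample in a group and assumes that it varies like the others. Chosen after the data were seen were the treatment of the empty part of 1 library as missing and, as its alternative, keeping its zeros, the treatment of isolated zeros as missing, a block within the MRTFB groups, a fit of the MRTFB groups alone with that block, and the lists without Puro vector replicate 1.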

Results

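RNA was sequenced from MCF-10A cells, an immortalised, non-tumorigenic human mammary epithelial line, on day 2 after retroviral infection. The 14 libraries form 7 groups of 2: the empty Hygro vector, YAP 5SA (a hyperactive form of the TEAD coactivator YAP), the empty Puro vector, and 4 forms of the SRF coactivator MRTFB. MRTFB dN cannot bind G-actin, MRTFB dN dPY also lacks YAP binding, MRTFB dN Y305A also lacks SRF binding, and MRTFB dN Y305A/dPY lacks both. The introduced genes were visible in the RNA: MKL2, the table's symbol for MRTFB, stood between 165 and 610 FPKM in the 8 MRTFB libraries against 3.66 and 6.6 in the Puro vector, and YAP1 stood at 625 and 529 FPKM in YAP 5SA against 32.4 and 23.3 in the Hygro vector. The MKL2 level was not the same in all MRTFB groups. In replicates 1 and 2 it was 300 and 165 FPKM in MRTFB dN and 286 and 171 in MRTFB dN dPY. It was 404 and 294 in MRTFB dN Y305A, and 610 and 343 in MRTFB dN Y305A/dPY. The comparisons between these groups were not adjusted for it. The table gives no counts, so absolute depth is unknown. The most frequent ratio between the lowest values of each library puts relative depth between 0.32 (Puro vector replicate 1) and 1.41 (YAP 5SA replicate 1), with Hygro vector replicate 1 at 1.

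The first 2 principal components held 39.9% and 21.7% of the variance, and the first set the MRTFB dN and MRTFB dN dPY libraries apart from all others. In each of the 4 MRTFB groups replicate 1 lay above replicate 2 on the second component. Puro vector replicate 1 stood apart from every other library: 4780 unnamed loci reached 1 FPKM in it, against 211 to 669 elsewhere, and 58.77% of its FPKM sum lay in unnamed loci, against 9.99% to 38.57%. MRTFB dN dPY replicate 1 has no value above 0 after PPIA on chromosome 7 or on chromosomes 8, 9 and X. Its 5235 loci there were treated as missing, so a gene in that part rests on 1 library in this group. The labels do not say whether the replicates are separate cultures. Group sizes below are n = 2 libraries, errors are the SE of the log2 fold change from limma, and folds are on FPKM + 1.

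YAP 5SA was compared with the Hygro vector to see which genes hyperactive YAP changes in these cells. YAP/TEAD targets rose. ANKRD1 rose by 4.97 ± 0.35 on the log2 scale (adjusted p = 5.1e-05), from 0.422 and 0.457 FPKM to 54.6 and 35.5. The matricellular genes CYR61 and CTGF rose by 3.84 ± 0.60 (adjusted p = 0.0049) and 3.43 ± 0.57 (adjusted p = 0.0061), and AMOTL2, an angiomotin family member that restrains YAP, by 1.71 ± 0.33 (adjusted p = 0.011). Of the 33 measured YAP/TEAD targets 16 rose and none fell, 20 adjusted over the list alone, with a median log2 fold change of 1.69 (camera adjusted p = 7.6e-13, and adjusted p = 0.00047 with an estimated correlation). TEAD1 itself rose 5.23-fold (adjusted p = 0.0025). Large increases outside that list were those of OLR1, a lectin-like scavenger receptor (43.5-fold), MFAP5, a microfibril glycoprotein (43.4-fold), and RGCC (31.6-fold). The short locus MIR4516, whose FPKM can rest on few reads, went from listed at 0 in both Hygro libraries to 994 and 1280 FPKM (adjusted p = 0.049), with 7490 FPKM in Puro vector replicate 1. Its call was lost with no filter (adjusted p = 0.12), after scaling by the median of ratios (adjusted p = 0.053) and against the Puro vector (3.71, adjusted p = 0.42).

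Squamous differentiation genes, which mark the cornifying layers of stratified epithelia, fell in YAP 5SA. The calprotectin subunits S100A9 and S100A8 fell 55.7-fold (adjusted p = 4.6e-05) and 114-fold (adjusted p = 0.0072), and the epidermal protease gene KLK7 changed by -5.32 ± 1.27 (adjusted p = 0.028). Of 22 squamous differentiation genes 12 fell (18 adjusted over the list alone), with a median of -3.07 (camera adjusted p = 7.6e-13, and adjusted p = 0.027 with an estimated correlation). Of 22 epithelial junction genes 8 fell (13 adjusted over the list alone, median -1.18), including the tight junction claudins CLDN4 (15.3-fold) and CLDN7 (5.01-fold). Their camera adjusted p of 1.5e-05 became an adjusted p of 0.12 with an estimated correlation. ELF3, an epithelial transcription factor of the luminal list, fell 10.4-fold (adjusted p = 0.00088). Mitosis genes rose in 10 of 25 (17 adjusted over the list alone, median 1.37, camera adjusted p = 3.3e-12, but adjusted p = 0.21 with an estimated correlation), among them CENPF (3.59-fold) and HMMR (4.03-fold). DNA replication genes rose in 5 of 26 (6 adjusted over the list alone, median 0.80, camera adjusted p = 6.3e-07, but adjusted p = 0.42 with an estimated correlation). Of 33 MRTF/SRF targets 1 rose, the tropomyosin gene TPM1 (5.38-fold, adjusted p = 0.043), with a list median of -0.07 (camera adjusted p = 0.69). The list has no stable direction: its median was -0.65 without Hygro vector replicate 1 (camera adjusted p = 0.02), 0.55 without Hygro vector replicate 2 (camera adjusted p = 0.00043) and 1.01 against the Puro vector (camera adjusted p = 0.001). TPM1 did not pass without Hygro vector replicate 1 (1.28, adjusted p = 0.18) or without either YAP 5SA library (adjusted p = 0.18 and 0.21). Of 6 leukocyte markers none passed over all genes and 4 fell adjusted over the list alone (median -1.23, camera adjusted p = 0.024, but adjusted p = 0.052 with an estimated correlation). Of 24 interferon response genes none passed in either way (median -2.36, camera adjusted p = 1.8e-05, but adjusted p = 0.55 with an estimated correlation).

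Named short RNA loci held 34.05% and 31.75% of the FPKM sum in YAP 5SA, against 72.33% and 61.23% in the Hygro vector. The cause of this difference was not tested. In all, 516 of 13137 genes were higher and 570 lower in YAP 5SA. These counts rest on few libraries: they were 102 and 121 without YAP 5SA replicate 1, 85 and 56 without YAP 5SA replicate 2, 228 and 301 without Hygro vector replicate 1, and 101 and 75 when the 4 compared libraries were fitted alone. Of the 28 named genes that passed, 18 lost the call without 1 of the 4 libraries, including CTGF (2.94, adjusted p = 0.063), CYR61 (3.41, adjusted p = 0.053) and AMOTL2 (1.5, adjusted p = 0.097) without YAP 5SA replicate 1. Against the Puro vector instead, YAP/TEAD targets still rose in 16 of 33 (median 1.53), while 3 squamous and 1 junction gene fell, 1 mitosis gene rose, and KLK7 (0.79), CENPF (-0.40), ELF3 (-0.46), CLDN4 (-1.61), CLDN7 (-1.08) and HMMR (0.78) did not pass.

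MRTFB dN was compared with the Puro vector to see which genes MRTFB freed from G-actin switches on. Smooth muscle and cardiac contractile genes were among the largest increases. ACTG2 went from 1.2 and 1.12 to 59800 and 36400 FPKM (log2 fold change 14.40 ± 0.48, adjusted p = 1.7e-08), ACTA2 from 4.26 and 7.25 to 52300 and 30900 FPKM (12.58 ± 0.41, adjusted p = 1.7e-08), and the locus PAFAH1B2,SIDT2,TAGLN, which holds the smooth muscle gene transgelin, from 28.2 and 25.5 to 41600 and 22300 FPKM (10.10 ± 0.67, adjusted p = 2.4e-06). ACTC1 rose by 10.92 ± 0.19, and the myosin light chain gene MYL9 by 10.34 ± 0.70. SRF itself rose by 3.58 ± 0.35. Actin genes are near-identical in their coding parts, so reads assigned to one may belong to another. CNN1, another smooth muscle gene, was at 0 in 13 of the 14 libraries. Of 33 MRTF/SRF targets 30 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 4.06 (camera adjusted p = 5.2e-18, but adjusted p = 0.17 with an estimated correlation).

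Genes of the YAP/TEAD list rose with them in MRTFB dN. Membership in that list does not show that YAP or TEAD raised them. In MRTFB dN Y305A, which lacks SRF binding, ANKRD1 and CTGF were lower than in MRTFB dN, while CYR61 and AMOTL2 did not pass (below). CTGF rose 1150-fold, from 1.12 and 6.54 to 4710 and 4470 FPKM (10.16 ± 0.57, adjusted p = 7.8e-07), ANKRD1 749-fold (9.55 ± 0.35, adjusted p = 3.6e-08), CYR61 190-fold (7.57 ± 0.60, adjusted p = 9.2e-06) and AMOTL2 5.16-fold (2.37 ± 0.33, adjusted p = 0.00044). Of 33 YAP/TEAD targets 16 rose and 1 fell (17 and 3 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 0.00011, but adjusted p = 0.17 with an estimated correlation). TEAD1 rose 3.35-fold and WWTR1, which encodes the YAP paralog TAZ, 3.88-fold. Against the Hygro vector 28 MRTF/SRF targets rose and none fell, 14 YAP/TEAD targets rose and 1 fell, and AMOTL2 did not pass (0.83, adjusted p = 0.10).

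Further groups moved in MRTFB dN. Integrin and focal adhesion genes rose in 13 of 21 and fell in 2, with the same numbers adjusted over the list alone, including the kindlin gene FERMT2 (23.7-fold) and the loci ITGA5,ZNF385A (66.9-fold) and ITGA1,PELO (28.3-fold). TGF-beta and SMAD targets rose in 9 of 15 (9 adjusted over the list alone), led by the activin subunit INHBA (36.0-fold). Genes of cholesterol metabolism rose in 14 of 22 (15 adjusted over the list alone), with IDI1 at 7.12-fold, and hypoxia and glycolysis genes rose in 13 of 19 and fell in 1, as they did adjusted over the list alone, with the vasodilator gene ADM at 10.1-fold. Extracellular matrix genes rose in 9 of 18 and fell in 1 (9 and 2 adjusted over the list alone). The camera adjusted p values were 0.00011, 0.003, 0.00011, 0.017 and 0.043, and with an estimated correlation the adjusted p values were 0.24, 0.38, 0.24, 0.38 and 0.71. Mesenchymal genes went both ways, with 6 of 13 higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.22), and VIM and FN1 among them rose 84.5-fold and 68.1-fold. S100A9 and S100A8 fell 101-fold and 120-fold, and p53 targets rose in 3 of 22 and fell in 6 (the same numbers adjusted over the list alone, camera adjusted p = 0.33), with CDKN1A higher 10.4-fold and GDF15 lower 24.8-fold. Mitosis genes fell in 7 of 25 (6 adjusted over the list alone, median -0.88, camera adjusted p = 0.00034, but adjusted p = 0.65 with an estimated correlation), among them CENPF (5.72-fold). In contrast, DNA replication genes rose in 4 of 26 (0 adjusted over the list alone, median 0.39, camera adjusted p = 0.60). The 5 largest decreases were short nucleolar RNA loci, whose FPKM can rest on few reads (SNORD35B, SNORD88A, SNORD12B, SNORD88C and SNORD67), listed at 0 in both MRTFB dN libraries. Of these SNORD12B, SNORD88C and SNORD67 did not pass against the Hygro vector (-4.48, -4.70 and -3.17, adjusted p = 0.28, 0.26 and 0.40), without Puro vector replicate 1 (adjusted p = 0.073, 0.09 and 0.10) or without either MRTFB dN library.

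Of 13137 genes 2868 were higher and 1969 lower in MRTFB dN. Without MRTFB dN replicate 1 the counts were 1399 and 618, and without Puro vector replicate 1, the library with the many unnamed loci, 2041 and 1157. In that fit 5 hypoxia and glycolysis genes rose and 3 fell, and 4 extracellular matrix genes rose and 1 fell. Against the Hygro vector the counts were 1576 and 932. There 4 cholesterol genes rose and 1 fell, 15 squamous differentiation genes fell, against 3 that rose and 4 that fell in the comparison with the Puro vector, 7 epithelial junction genes fell and 2 rose, no mitosis gene passed (median 0.19), and CDKN1A (0.72, adjusted p = 0.24) and IDI1 (0.8, adjusted p = 0.33) did not pass. Scaling each library by the median of ratios gave 2242 higher and 2696 lower, as it moved the median of all genes from 0.09 to -0.15. The same scaling moved that median from 0.07 to -0.15 for MRTFB dN dPY, from 0.10 to -0.17 for MRTFB dN Y305A, from 0.08 to -0.16 for MRTFB dN Y305A/dPY, and from -0.07 to 0.13 for the Puro against the Hygro vector, so the balance of higher and lower genes in comparisons with the Puro vector depends on the scaling.

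**Figure D1:**
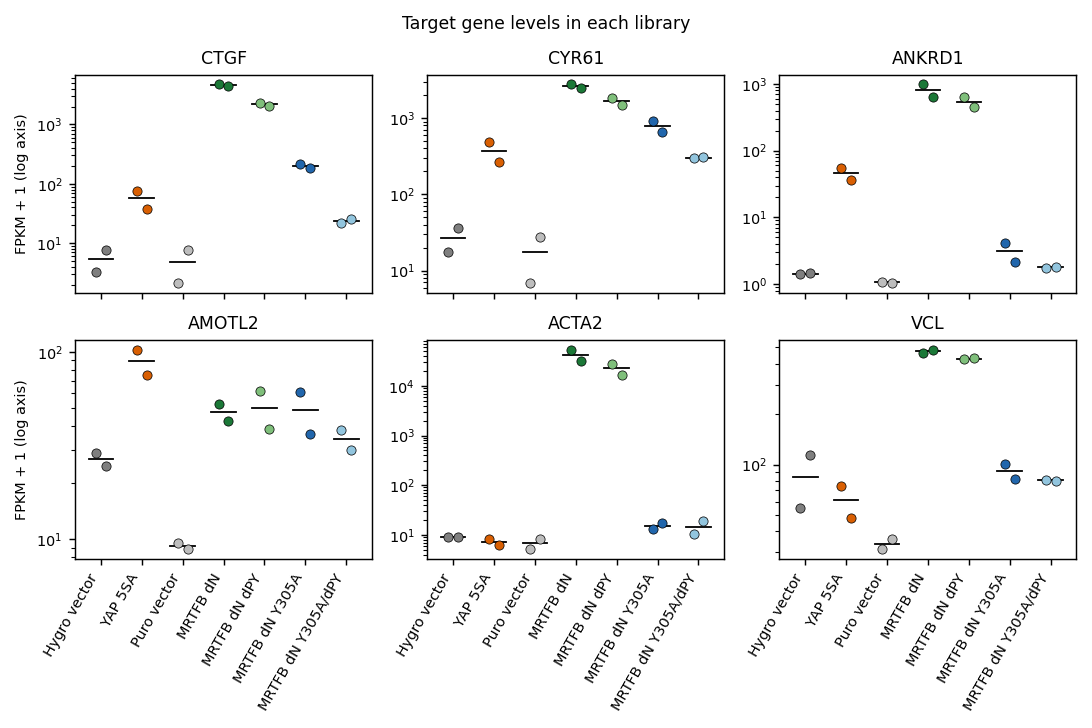
Level (FPKM + 1, log axis) of 6 target genes in each of the 14 libraries by group, with points for libraries and a line for the group mean. CTGF stands between 2080 and 4710 FPKM in MRTFB dN and MRTFB dN dPY, at 184 and 213 in MRTFB dN Y305A, and at 21.2 and 24.6 in MRTFB dN Y305A/dPY.

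The overlap of the YAP 5SA and MRTFB dN responses bears on whether MRTFB acts on genes that YAP controls. Both raised 171 genes, against 112.7 for independent responses, and both lowered 120, against 85.4. Opposite directions also occurred: 83 genes were higher in YAP 5SA and lower in MRTFB dN (77.3 for independent responses), and 138 were lower and higher (124.4). Across genes the log2 fold changes of these comparisons, which share no library, had a Pearson r of 0.002 and a Spearman rho of -0.108. Their controls were different vectors, which differed from each other in 1870 genes. The overlap and these correlations can depend on that, and neither was computed against a common vector. Genes are not independent replicates, so no p is given. In the refits that follow fewer genes were called, so the number for independent calls changes too, and it was not computed. The overlap was 43 without YAP 5SA replicate 1, 39 without YAP 5SA replicate 2, 82 without Hygro vector replicate 1, 105 without MRTFB dN replicate 1, and 24 when the compared groups were fitted alone.

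MRTFB dN dPY was compared with the Puro vector and with MRTFB dN to see what loss of YAP binding changes. In the former comparison MRTF/SRF and YAP/TEAD targets rose. ACTG2 stood at 68500 and 46000 FPKM, ACTA2 at 27900 and 16800 and ACTC1 at 3030 and 2710, and CTGF rose 542-fold (9.08 ± 0.57, adjusted p = 1.7e-06), ANKRD1 504-fold and CYR61 119-fold. Of 33 MRTF/SRF targets 30 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 4.03 (camera adjusted p = 1.7e-16, but adjusted p = 0.22 with an estimated correlation), and of 33 YAP/TEAD targets 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 0.00012, but adjusted p = 0.22 with an estimated correlation). Mitosis genes fell in 23 of 25, also adjusted over the list alone, with a median of -2.33 (camera adjusted p = 1e-11, but adjusted p = 0.26 with an estimated correlation), including CENPF (10.9-fold), the topoisomerase gene TOP2A (8.85-fold) and the proliferation marker MKI67 (8.11-fold). DNA replication genes fell in 7 of 26, also adjusted over the list alone (median -0.76, camera adjusted p = 0.004, but adjusted p = 0.61 with an estimated correlation). Against the Hygro vector 7 mitosis genes fell (median -1.19), and the mitosis gene TOP2A did not pass (-1.29, adjusted p = 0.14).

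Of 13137 genes 2762 were higher and 1946 lower in MRTFB dN dPY than in the Puro vector. The counts were 1596 and 821 without MRTFB dN dPY replicate 1, 2007 and 1232 without Puro vector replicate 1, 1616 and 1084 against the Hygro vector, and 2171 and 2628 after scaling by the median of ratios. Of the genes higher in MRTFB dN, 2436 were also higher in MRTFB dN dPY, against 603 for independent calls, and the log2 fold changes had an r of 0.951 across genes. The shared Puro libraries alone gave an r of 0.484 in 50 simulated draws without any group difference. The covariance of the log2 fold changes was 1.711 in the data and 0.097 in those draws. The 0.484 is therefore not the part of the observed r that the shared libraries explain.

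Set against MRTFB dN directly, MRTFB dN dPY differed in 31 genes of 13137, 19 higher and 12 lower, with 438 at an unadjusted p under 0.05, against 657 for no difference anywhere. So low a number can mean that the spread, which is shared with the vector libraries, is too large for this comparison. Libraries of MRTFB dN and MRTFB dN dPY with the same replicate number had an r of 0.977 and 0.969. Replicates within these groups had 0.96 and 0.958, and the fit without a block counts this replicate difference as spread. None of the fixed YAP/TEAD genes passed: CTGF differed by -1.08 ± 0.57, CYR61 by -0.67 ± 0.60, ANKRD1 by -0.57 ± 0.35 and AMOTL2 by 0.04 ± 0.33, all with an adjusted p of 1. The YAP/TEAD list had a median of -0.06 and 0 of 33 members passed (camera adjusted p = 0.52), and the MRTF/SRF list had a median of -0.04 (camera adjusted p = 0.25), where only FHL1, a LIM domain gene of muscle measured in 1 MRTFB dN dPY library, fell (6.05-fold, adjusted p = 0.0063). Without MRTFB dN dPY replicate 1 the MRTF/SRF list passed as lower (median -0.125, camera adjusted p = 0.0079). JAKMIP1, a microtubule-associated gene, rose 5.67-fold (2.50 ± 0.17, adjusted p = 0.00013) and the peroxisomal transporter gene ABCD2 3.35-fold (adjusted p = 0.0038). LY86 fell 4.6-fold (-2.20 ± 0.18, adjusted p = 0.0006), the growth factor gene IGF1 4.47-fold (adjusted p = 0.0082) and the natriuretic peptide gene NPPB 4.90-fold (adjusted p = 0.037), from 1110 and 1300 to 404 and 149 FPKM. The short locus MIR554, whose FPKM can rest on few reads, went from 733 and 575 FPKM to listed at 0. As lists, mitosis genes had a median of -1.29 with all 25 members below 0. None passed over all genes, 20 fell adjusted over the list alone, and the camera adjusted p was 4e-36, with an adjusted p of 0.024 with an estimated correlation. DNA replication genes had a median of -0.94 (0 of 26 over all genes, 3 fell adjusted over the list alone, camera adjusted p = 3e-27, and adjusted p = 0.03 with an estimated correlation).

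The higher and lower counts were 2 and 3 without MRTFB dN replicate 1, 4 and 5 without MRTFB dN replicate 2, 3 and 7 without MRTFB dN dPY replicate 1, and 8 and 3 without MRTFB dN dPY replicate 2. Of the 11 named genes that passed, 10 lost the call with a pseudocount of 0.1 and 10 with the compared groups fitted alone, including JAKMIP1 in both (adjusted p = 0.32 and 0.21). Without 1 library 6 lost it, among them NPPB (-1.57, adjusted p = 0.11) and IGF1 (-1.94, adjusted p = 0.071) without MRTFB dN dPY replicate 2. The mitosis median was -0.87 without MRTFB dN dPY replicate 1 and -1.72 without MRTFB dN dPY replicate 2. On simulated data 7.1% of changes of 1 on the log2 scale and 72.2% of changes of 2 were called here, so a difference of the size seen for CTGF would mostly be missed here. In a fit of the MRTFB groups alone with the replicate number as a block, chosen after the data were seen, 15 genes were higher and 13 lower, with 1310 at an unadjusted p under 0.05. There CTGF differed by -1.08 ± 0.14 (adjusted p = 0.08) and CYR61 by -0.67 ± 0.17 (adjusted p = 0.26), and NPPB did not pass (adjusted p = 0.14).

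**Figure D2:**
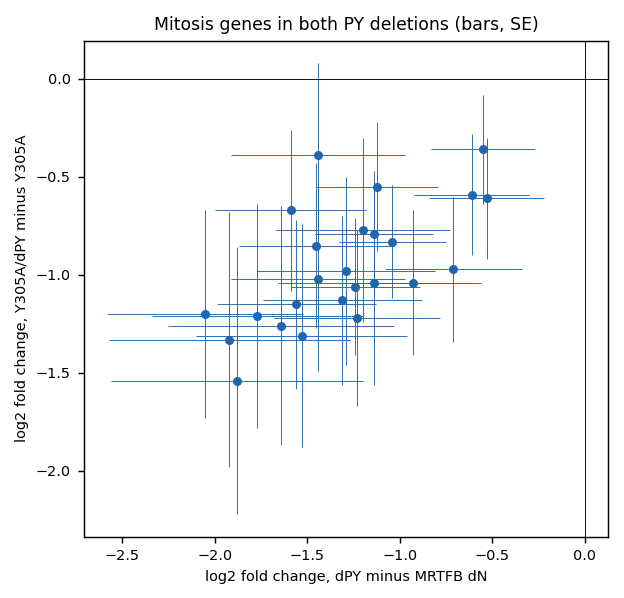
Log2 fold change of each of 25 mitosis genes in MRTFB dN dPY minus MRTFB dN (horizontal axis) and in MRTFB dN Y305A/dPY minus MRTFB dN Y305A (vertical axis), with bars for the SE. All points lie below 0 on both axes, with medians of -1.29 and -1.02.

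MRTFB dN Y305A was compared with the Puro vector and with MRTFB dN to see what loss of SRF binding changes. Against MRTFB dN, the contractile genes fell: ACTG2 to 0.789 and 0.872 FPKM (log2 fold change -14.64 ± 0.48, adjusted p = 1.9e-08), ACTA2 to 12.2 and 16.5 (-11.37 ± 0.41, adjusted p = 3.6e-08), ACTC1 to 0.0896 and 0.0705, and PAFAH1B2,SIDT2,TAGLN to 35 and 21.6 FPKM (-10.06 ± 0.67, adjusted p = 2.7e-06). Of 33 MRTF/SRF targets 27 fell and none rose (29 adjusted over the list alone), with a median of -2.90 (camera adjusted p = 6e-21, but adjusted p = 0.12 with an estimated correlation). YAP/TEAD genes split. ANKRD1 fell 266-fold (-8.06 ± 0.35, adjusted p = 1.1e-07), CTGF 23.1-fold (-4.53 ± 0.57, adjusted p = 0.00028) and the endothelin gene EDN1 29.2-fold, while CYR61 (-1.75 ± 0.60, adjusted p = 0.074) and AMOTL2 (-0.01 ± 0.33, adjusted p = 1) did not pass. In that list 11 of 33 fell and 1 rose (17 and 4 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 0.0002, but adjusted p = 0.12 with an estimated correlation).

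Further groups were lower in MRTFB dN Y305A than in MRTFB dN. Extracellular matrix genes fell in 11 of 18 and rose in 1, mesenchymal genes fell in 8 of 13 and rose in 2, hypoxia and glycolysis genes fell in 9 of 19 and rose in 1, TGF-beta and SMAD targets fell in 7 of 15 and rose in 1, and integrin and focal adhesion genes fell in 9 of 21 and rose in 3. Adjusted over the list alone the numbers that fell and rose were 12 and 1, 8 and 2, 10 and 2, 9 and 1, and 11 and 5. FN1 fell 104-fold, VIM 52.1-fold, INHBA 134-fold and FERMT2 31.6-fold. Their camera adjusted p values were 0.0002, 0.0045, 0.00064, 0.00047 and 0.003, and with an estimated correlation the adjusted p values were 0.31, 0.41, 0.14, 0.31 and 0.31. Inflammatory genes of the NF-kB list rose in 8 of 21 and fell in 3 (9 and 3 adjusted over the list alone), with the cytokine gene LIF at 32.5-fold and the chemokine genes CXCL1 and CXCL8 at 31.5-fold and 27.2-fold (camera adjusted p = 0.0098, but adjusted p = 0.62 with an estimated correlation). MYC and ribosome biogenesis genes rose in 6 of 18 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0002, but adjusted p = 0.12 with an estimated correlation), and MYC itself rose 4.8-fold. Leukocyte markers rose in 2 of 6, also adjusted over the list alone (median 0.68, camera adjusted p = 0.033, but adjusted p = 0.12 with an estimated correlation). Of 24 interferon response genes none passed in either way (median 1.49, camera adjusted p = 0.0098, but adjusted p = 0.76 with an estimated correlation). The largest increases included the metallothionein genes MT1E (158-fold) and MT2A (135-fold), which bind metal ions and have close paralogs, S100A9 (56.4-fold) and the urokinase gene PLAU (51.8-fold). Of 13137 genes 804 were higher and 1388 lower. The counts were 392 and 891 without MRTFB dN replicate 1, 354 and 903 without MRTFB dN replicate 2, 437 and 976 without MRTFB dN Y305A replicate 1, and 452 and 865 without MRTFB dN Y305A replicate 2. The CXCL1 call was lost without the last of these (3.77, adjusted p = 0.11) and without MRTFB dN replicate 1 (4.32, adjusted p = 0.10). The CXCL8 call was lost without each of the 4 in turn (adjusted p = 0.12, 0.088, 0.11 and 0.066). With the MRTFB groups fitted alone and the replicate number as a block 2351 genes were higher and 2512 lower, and CYR61 passed (adjusted p = 0.0013).

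Against the Puro vector, some YAP/TEAD targets were higher in MRTFB dN Y305A. CYR61 rose 56.6-fold (5.82 ± 0.60, adjusted p = 0.00067) and CTGF 49.7-fold (5.63 ± 0.57, adjusted p = 0.00067). AMOTL2 rose 5.12-fold and ANKRD1, at 3.2 and 1.11 FPKM, 2.81-fold. Of 33 YAP/TEAD targets 7 rose and 1 fell (7 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.17), and of 33 MRTF/SRF targets 11 rose and 1 fell (13 and 1 adjusted over the list alone), including ACTB (7.35-fold) and the myosin gene MYH9 (5.62-fold), with a median of 1.15 (camera adjusted p = 0.0035, but adjusted p = 0.98 with an estimated correlation). ACTA2 (1.21 ± 0.41, adjusted p = 0.054) and PAFAH1B2,SIDT2,TAGLN (0.03 ± 0.67, adjusted p = 0.98) did not pass, and the sign of the latter turned after scaling by the median of ratios (-0.34). Also higher were KRT80, an epithelial keratin (115-fold), IGFL1 (127-fold), LIF (46.3-fold) and CLDN4 (14-fold), and lower were TP63, the basal lineage transcription factor (5.85-fold), and the mesenchymal transcription factor genes SNAI2 (5.90-fold) and TWIST1 (3.27-fold). The mesenchymal list went both ways, with 2 of 13 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.67). Epithelial junction genes rose in 9 of 22 (camera adjusted p = 0.044, but adjusted p = 0.98 with an estimated correlation) and cholesterol synthesis genes in 11 of 22 (camera adjusted p = 3.1e-05, but adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone 9 junction genes rose and 1 fell, and 12 cholesterol synthesis genes rose. Interferon response genes rose in 8 of 24 (19 adjusted over the list alone), with a median of 3.70 (camera adjusted p = 3.1e-05, but adjusted p = 0.98 with an estimated correlation).

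Much of this comparison rests on the choice of vector and on single libraries. The counts were 1865 higher and 1445 lower of 13137, but 175 and 168 against the Hygro vector, 573 and 375 without Puro vector replicate 1, 83 and 50 without MRTFB dN Y305A replicate 1, and 1111 and 2152 after scaling by the median of ratios. With the compared groups fitted alone, which leaves fewer degrees of freedom, 3 and 4 genes passed, and CTGF, CYR61 and AMOTL2 did not (adjusted p = 0.13 each) although their folds did not move. With the Hygro vector as control CTGF and CYR61 still rose, AMOTL2 (0.82, adjusted p = 0.28), IGFL1 (3.01, adjusted p = 0.15), CLDN4 (1.48, adjusted p = 0.38) and TWIST1 (-0.09, adjusted p = 0.91) did not pass, 3 YAP/TEAD targets rose and 1 fell, and no MRTF/SRF target, cholesterol synthesis gene or interferon response gene passed. ANKRD1 (1.00, adjusted p = 0.15), ACTB (2.45, adjusted p = 0.16), MYH9 (2.17, adjusted p = 0.067) and CLDN4 (2.99, adjusted p = 0.079) were lost without MRTFB dN Y305A replicate 1. Without Puro vector replicate 1, 2 MRTF/SRF targets rose and 1 fell, 2 junction genes and 8 cholesterol synthesis genes rose, and no interferon response gene passed.

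**Figure D3:**
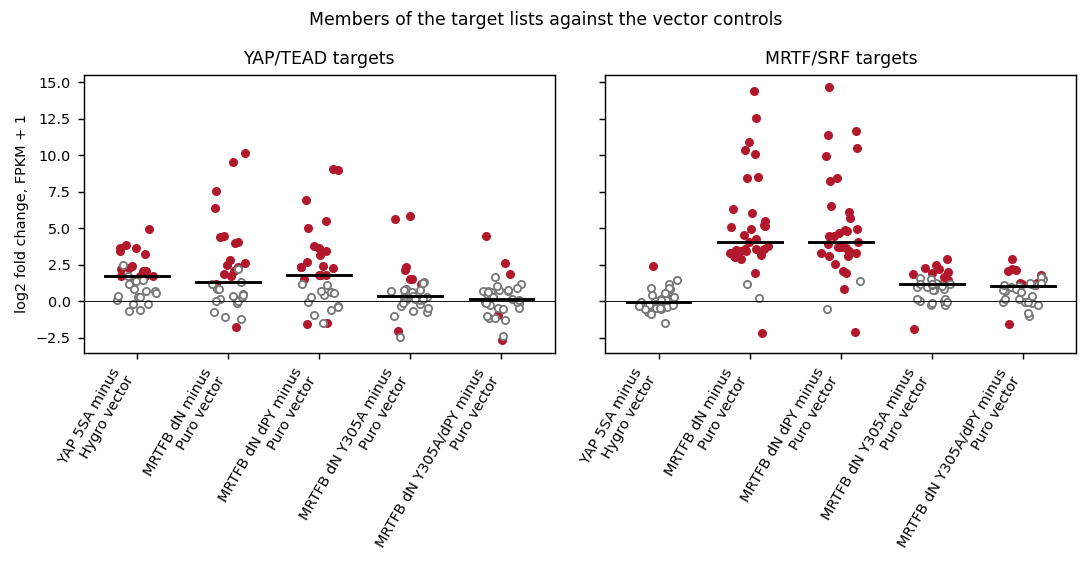
Log2 fold change against the vector control of each measured member of the YAP/TEAD list (33 genes) and the MRTF/SRF list (33 genes) in the 5 overexpression groups. Filled points have an adjusted p under 0.05 and the line is the list median, which for MRTF/SRF targets is 4.06 in MRTFB dN, 4.03 in MRTFB dN dPY, 1.15 in MRTFB dN Y305A and 1.06 in MRTFB dN Y305A/dPY.

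The 2868 genes higher in MRTFB dN than in the Puro vector were split by the mutant that lowered them. None was lower in MRTFB dN dPY only, 1142 (39.8%) were lower in MRTFB dN Y305A only, 12 (0.4%) in both, and 1714 (59.8%) in neither. In limma, 438 genes of all 13137 had an unadjusted p under 0.05 between MRTFB dN dPY and MRTFB dN. Simulated mutants equal to MRTFB dN gave at most 1, 1 and 0 genes in the first 3 classes in 50 draws. These draws took the noise of each gene independently, without the replicate differences that the MRTFB groups share. They therefore cannot show that the class of both exceeds chance. That class held 1 gene with a pseudocount of 0.1, and 1 with the compared groups fitted alone. Of the YAP/TEAD list 10 genes were lower in MRTFB dN Y305A only, 6 in neither and 17 were not higher in MRTFB dN, while 26 MRTF/SRF targets were lower in MRTFB dN Y305A only, 1 in both and 3 in neither. Of the 171 genes higher in both YAP 5SA and MRTFB dN, 128 (74.9%) were lower in MRTFB dN Y305A and 43 (25.1%) in neither mutant. A gene lower in neither was not shown to be independent of both partners. Nor was a gene lower in MRTFB dN Y305A only shown to be independent of YAP binding. Against MRTFB dN, 31 genes passed in MRTFB dN dPY and 2192 in MRTFB dN Y305A, so the adjusted threshold was stricter for the former. In the former, 7.1% of simulated changes of 1 on the log2 scale were called. CTGF, at -1.08 in MRTFB dN dPY minus MRTFB dN, did not pass there and counts as lower in MRTFB dN Y305A only. The split rests on calls against the Puro vector and was not repeated with the Hygro vector. Between the vectors 1123 genes were lower in Puro, so the class of neither can hold genes that are low in that vector. The classes lowered by Y305A only, by both and by neither held 714, 3 and 682 genes without MRTFB dN replicate 1, and the last held 889 without Puro vector replicate 1. The first held 756 without MRTFB dN Y305A replicate 2, and the class of both held 3 or 4 without MRTFB dN dPY replicate 2 or MRTFB dN replicate 2 and 7 without MRTFB dN dPY replicate 1 or either MRTFB dN Y305A replicate.

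MRTFB dN Y305A/dPY was compared with the Puro vector and with MRTFB dN Y305A to see what is left, and what YAP binding adds, once SRF binding is lost. Against the Puro vector CYR61 rose 21.9-fold (4.45 ± 0.60, adjusted p = 0.0022), CTGF 5.96-fold (2.58 ± 0.57, adjusted p = 0.011), to 21.2 and 24.6 FPKM, and AMOTL2 3.68-fold, while ANKRD1 (0.76 ± 0.35, adjusted p = 0.13) and ACTA2 (1.07 ± 0.41, adjusted p = 0.077) did not pass. With the compared groups fitted alone CYR61 (adjusted p = 0.099), CTGF (adjusted p = 0.14) and AMOTL2 (adjusted p = 0.1) did not pass either. Of 33 YAP/TEAD targets 3 rose and 2 fell, also adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.80), and of 33 MRTF/SRF targets 9 rose and 1 fell, also adjusted over the list alone, with a median of 1.06 (camera adjusted p = 0.023, but adjusted p = 0.98 with an estimated correlation). Interferon response genes rose in 22 of 24 (24 adjusted over the list alone), with a median of 5.06 (camera adjusted p = 8.4e-09, but adjusted p = 0.75 with an estimated correlation), with IFI27 at 2760 and 1730 FPKM and ISG15 at 2260 and 1770. The level of ISG15 varied within the Hygro vector, at 1640 and 34.3 FPKM, and no interferon gene passed against that vector (median 2.47). Mitosis genes fell in 14 of 25 (15 adjusted over the list alone, median -1.46, camera adjusted p = 6e-08, but adjusted p = 0.75 with an estimated correlation).

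In this comparison 1971 genes were higher and 1498 lower. The counts were 170 and 181 against the Hygro vector, 841 and 586 without Puro vector replicate 1, 244 and 127 without MRTFB dN Y305A/dPY replicate 1, 27 and 7 with the compared groups fitted alone, and 1237 and 2070 after scaling by the median of ratios. CTGF did not pass without Puro vector replicate 1 (1.66, adjusted p = 0.068), without MRTFB dN Y305A/dPY replicate 1 (2.68, adjusted p = 0.072) or against the Hygro vector (2.26, adjusted p = 0.067). AMOTL2 did not pass against the Hygro vector (0.34, adjusted p = 0.69) or without MRTFB dN Y305A/dPY replicate 1 (1.70, adjusted p = 0.054). Without Puro vector replicate 1 there were 5 interferon genes that rose and 8 mitosis genes that fell. The MRTF/SRF median was 0.745 without Puro vector replicate 1 and did not pass (camera adjusted p = 0.11), and 0.689 without MRTFB dN Y305A/dPY replicate 1 (camera adjusted p = 0.036).

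Between MRTFB dN Y305A/dPY and MRTFB dN Y305A, 0 of 13137 genes were higher and 2 lower by limma, with 271 at an unadjusted p under 0.05. This is again under the 657 for no difference anywhere. The 2 were CES1, a carboxylesterase gene (-1.85 ± 0.19, adjusted p = 0.017), and LCE3D, a late cornified envelope gene (-2.32 ± 0.27, adjusted p = 0.028). CTGF stood at 213 and 184 FPKM in MRTFB dN Y305A and at 21.2 and 24.6 in the double mutant (-3.06 ± 0.57, adjusted p = 0.42), and CYR61 differed by -1.37 ± 0.60 (adjusted p = 1). As a list, YAP/TEAD targets had a median of -0.27 with 0 of 33 past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 1.7e-05, but adjusted p = 0.071 with an estimated correlation). MYC and ribosome biogenesis genes had a median of -0.32 with 0 of 18 past the threshold (camera adjusted p = 8.3e-08, and adjusted p = 0.043 with an estimated correlation), interferon response genes a median of 1.32 with 0 of 24 past it (camera adjusted p = 2.9e-09, but adjusted p = 0.36 with an estimated correlation), and mitosis genes a median of -1.02 with 0 of 25 past it (camera adjusted p = 4.1e-25, but adjusted p = 0.071 with an estimated correlation). Without MRTFB dN Y305A/dPY replicate 1 both single calls were lost (CES1 -1.82, adjusted p = 0.14, and LCE3D -1.93, adjusted p = 0.15), CES1 was also lost without MRTFB dN Y305A/dPY replicate 2 (adjusted p = 0.085), and LCE3D without MRTFB dN Y305A replicates 1 and 2 (adjusted p = 0.19 and 0.14). With the MRTFB groups fitted alone and the replicate number as a block, chosen after the data were seen, CTGF was lower in the double mutant (-3.06 ± 0.14, adjusted p = 0.0042). In that fit 2 genes were higher and 5 lower, with 1641 at an unadjusted p under 0.05, above the 657 for no difference anywhere. CYR61 (-1.37 ± 0.17, adjusted p = 0.16) and LCE3D (adjusted p = 0.077) did not pass there. The labels do not say that the replicate numbers pair the groups. Libraries of MRTFB dN Y305A and the double mutant with the same replicate number had an r of 0.971 and 0.966. Replicates within these groups had 0.954 and 0.947.

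Whether the PY deletion acted differently with and without SRF binding was tested as an interaction, in which 2 genes were above 0 and 1 below, with 254 at an unadjusted p under 0.05. The interaction was -1.97 ± 0.80 for CTGF and -0.70 ± 0.85 for CYR61, each with an adjusted p of 1. With the MRTFB groups fitted alone and the replicate number as a block, the SE of these values fell to 0.20 and 0.24 and the adjusted p to 0.10 and 0.60, with 4 genes above 0 and 2 below. There 992 genes had an unadjusted p under 0.05, above the 657 for no difference anywhere. A different effect of the PY deletion on CTGF thus stays open. As lists, with no member past the threshold over all genes or over the list alone, YAP/TEAD targets had a median interaction of -0.26 (camera adjusted p = 0.0094), interferon response genes 1.43 (3e-06), DNA replication genes 0.36 (0.00031) and mitosis genes 0.34 (0.016). With an estimated correlation the adjusted p values were 0.65, 0.65, 0.65 and 0.72. MIR554 (9.35 ± 0.27) and LY86 (2.20 ± 0.26) were the genes above 0 and JAKMIP1 (-2.45 ± 0.24) the gene below, and all had levels of 0 or below 0.1 FPKM in the 4 libraries without SRF binding. A drop could not be seen from 0 there, so the values of MIR554 and LY86 only restate the difference between MRTFB dN dPY and MRTFB dN. JAKMIP1 and LY86 did not pass with a pseudocount of 0.1 (adjusted p = 1 each).

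The vector controls, which carry no insert, also differed from each other. Of 13137 genes 747 were higher and 1123 lower in the Puro than in the Hygro vector. Squamous differentiation genes fell in 9 of 22 (10 adjusted over the list alone), epithelial junction genes in 8 of 22 (14 adjusted over the list alone), cholesterol synthesis genes in 8 of 22 (10 adjusted over the list alone) and MRTF/SRF targets in 8 of 33, with 1 that rose (11 and 1 adjusted over the list alone). Involucrin (IVL) fell 17.2-fold, KLK7 69.2-fold, ELF3 7.59-fold, the p53 target CDKN1A 6.32-fold and AMOTL2 2.90-fold (adjusted p = 0.017). Mitosis genes rose in 6 of 25 (9 adjusted over the list alone), with CENPF at 4.72-fold. CTGF (-0.31 ± 0.57, adjusted p = 0.73) and CYR61 (-0.86 ± 0.60, adjusted p = 0.34) did not pass. Camera adjusted p values were 4.6e-06 for squamous, 2.7e-05 for junction, 0.00021 for cholesterol, 0.0051 for MRTF/SRF and 9.2e-07 for mitosis genes, and with an estimated correlation the adjusted p values were 0.26, 0.26, 0.26, 0.73 and 0.51. Interferon response genes fell in 1 of 24 (0 adjusted over the list alone), with a median of -2.64 (camera adjusted p = 0.00013, but adjusted p = 0.65 with an estimated correlation). The luminal list, in which 3 of 10 fell (7 adjusted over the list alone), had a camera adjusted p of 0.0067 and an adjusted p of 0.044 with an estimated correlation.

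Between the vectors the counts were 356 and 418 without Puro vector replicate 1, 1173 and 1250 without Puro vector replicate 2, 357 and 940 without Hygro vector replicate 1, 137 and 302 without Hygro vector replicate 2, and 0 and 0 when the 4 libraries were fitted alone, and scaling by the median of ratios gave 1175 higher and 761 lower. Without Puro vector replicate 1, 1 MRTF/SRF target rose and none fell, 10 squamous genes fell, and 4 junction genes fell and 1 rose.

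**Figure D4:**
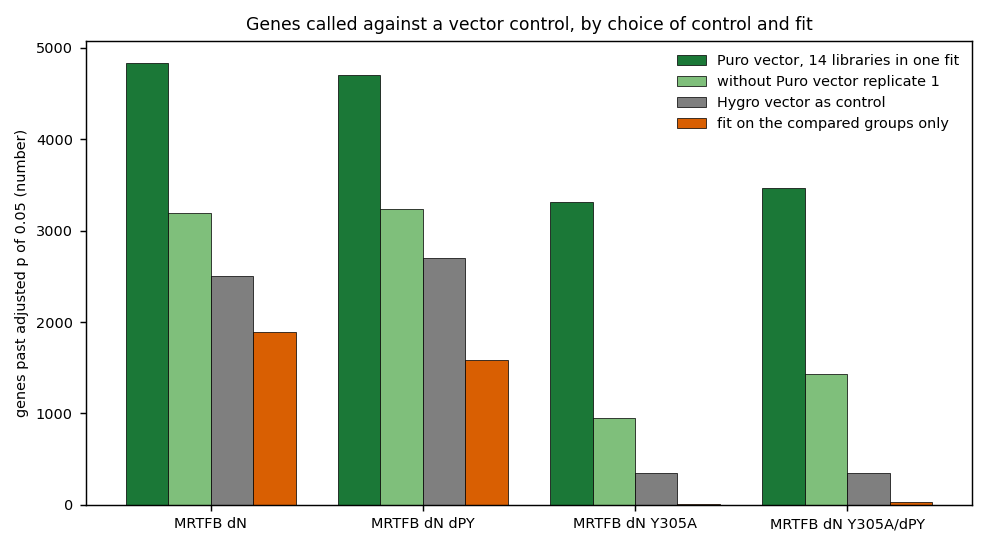
Number of genes, higher and lower together, with an adjusted p under 0.05 against a vector in the 4 MRTFB groups (bars from 0), with the Puro vector as control, without Puro vector replicate 1, with the Hygro vector as control, and with the compared groups fitted alone. In MRTFB dN Y305A the first 3 bars stand at 3310, 948 and 343 genes.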

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

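The interaction test of the PY deletion and the loss of SRF binding passed for 3 genes, all at 0 or below 0.1 FPKM in the 4 libraries without SRF binding. From such levels a further drop cannot be seen, so for MIR554 and LY86 the test only restates the difference between MRTFB dN dPY and MRTFB dN. MIR554 had an interaction of 9.35 ± 0.27 on the log2 scale (adjusted p = 2.5e-08), with 733 and 575 FPKM in MRTFB dN and 0 in the 6 libraries of the mutants. It is a short locus, so these FPKM values can rest on few reads, and no counts are given to tell. JAKMIP1 had -2.45 ± 0.24 (adjusted p = 0.0053), with 11.2 and 10.8 FPKM in MRTFB dN dPY against 1.03 and 1.21 in MRTFB dN. LY86 had 2.20 ± 0.26 (adjusted p = 0.018), with 6.2 and 8.11 FPKM in MRTFB dN against 0.723 and 0.802 in MRTFB dN dPY and 0 in the 4 libraries of the mutants that do not bind SRF. LY86 did not pass without MRTFB dN dPY replicate 1 (adjusted p = 0.078), or without any of the 4 libraries of the mutants that do not bind SRF (adjusted p = 0.081 to 0.13). With a pseudocount of 0.1 neither JAKMIP1 (-2.77) nor LY86 (3.06) passed (adjusted p = 1 each), and LY86 did not pass with the MRTFB groups fitted alone and a replicate block (adjusted p = 0.071).

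Loci without a gene name, which the comparisons leave out, also differed between groups, by a test chosen after the table was seen. Of 1239 unnamed loci tested, 286 were higher in MRTFB dN than in the Puro vector, 270 than in the Hygro vector, and 255 than in both, which share the MRTFB dN libraries. Lower were 346 than in the Puro and 45 than in the Hygro vector. The share higher than in the Puro vector, 23.1%, was close to the 21.8% of named loci.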

How the results depend on the processing

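The lists without Puro vector replicate 1, keeping the zeros of the empty part, isolated zeros as missing, the block within the MRTFB groups and the MRTFB groups alone with a block were chosen after the data were seen. No intensity trend and isolated zeros as missing left every count within 1.5 times and every target list median on its side of the threshold, and so did the block within the MRTFB groups for the comparisons among those groups and the classes by mutant, where alone it was run. With the MRTFB groups alone and a block, 2351 and 2512 genes differed between MRTFB dN Y305A and MRTFB dN, 2 and 5 between MRTFB dN Y305A/dPY and MRTFB dN Y305A, and 4 and 2 had an interaction. With the replicate number as a block over all libraries, 7 genes were lower in MRTFB dN dPY than MRTFB dN and 7 genes were in the class lowered by both mutants. Replicate differences correlated between MRTFB groups (0.32 to 0.64) and were at -0.15 to 0.07 between these and the other groups, and at 0.24 between the 2 vectors, so the numbers do not pair all libraries. Except where fewer samples or a changed control enter by construction, the cause was not tested.

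Fitting the compared groups only, with fewer libraries to estimate the spread, gave 101 higher and 75 lower genes in YAP 5SA than Hygro vector. Against the Puro vector it gave 1273 and 617 in MRTFB dN, 1049 and 532 in MRTFB dN dPY, 3 and 4 in MRTFB dN Y305A, and 27 and 7 in MRTFB dN Y305A/dPY. It gave 0 and 1 in MRTFB dN dPY against MRTFB dN, 513 higher in MRTFB dN Y305A against MRTFB dN, 0 and 0 in the Puro against the Hygro vector, 1 and 0 in MRTFB dN Y305A/dPY against MRTFB dN Y305A, and 4 positive and 2 negative interactions. The overlap was 24, and the classes lowered by Y305A only, both and neither held 655, 1 and 617.

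With the other vector as control the counts were 1576 and 932 in MRTFB dN, 1616 and 1084 in MRTFB dN dPY, 175 and 168 in MRTFB dN Y305A, and 170 and 181 in MRTFB dN Y305A/dPY. The MRTF/SRF median turned to 1.01 in YAP 5SA and passed (adjusted p = 0.001), and was 0.23 in MRTFB dN Y305A and 0.054 in MRTFB dN Y305A/dPY. In YAP 5SA the signs of ACTA2 (0.14), PAFAH1B2,SIDT2,TAGLN (1.88), VCL (0.83), KLK7 (0.79) and CENPF (-0.40) turned, and in MRTFB dN Y305A that of PAFAH1B2,SIDT2,TAGLN (-2.07). After scaling by the median of ratios 1111 genes were higher in MRTFB dN Y305A and 1237 in MRTFB dN Y305A/dPY than Puro vector, 1175 were higher in the Puro than the Hygro vector, 1 was lower in MRTFB dN Y305A/dPY than MRTFB dN Y305A, and 1132 were in the class lowered by neither. The YAP/TEAD median turned to -0.001 in MRTFB dN Y305A and -0.12 in MRTFB dN Y305A/dPY, and PAFAH1B2,SIDT2,TAGLN to -0.34 in MRTFB dN Y305A.

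With the zeros of the empty part kept, 362 genes were lower in YAP 5SA than Hygro vector, 486 and 712 were higher and lower in the Puro vector, 1 was lower in MRTFB dN Y305A/dPY than MRTFB dN Y305A, the overlap was 112, and the MRTF/SRF median of 1.06 in MRTFB dN Y305A/dPY did not pass. With a pseudocount of 0.1, 0 genes were higher and 1 lower in MRTFB dN dPY than MRTFB dN, 0 were lower in MRTFB dN Y305A/dPY than MRTFB dN Y305A, 1 and 0 had an interaction, and 1 was in the class of both. With no filter, 60 and 34 genes differed between MRTFB dN dPY and MRTFB dN, 8 and 18 had an interaction, 34 were in the class of both, and the YAP/TEAD median of 0.33 in MRTFB dN Y305A passed. With an estimated correlation the calls of the target list medians 1.33, 4.06, 1.81, 4.03, 1.15, 1.06, -0.92 and -2.90 were lost, and that of YAP/TEAD targets in YAP 5SA was not.

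With 1 library left out the higher and lower counts ranged over 85 to 365 and 56 to 399 in YAP 5SA than Hygro vector, 1399 to 2838 and 618 to 2047 in MRTFB dN, 1596 to 2713 and 821 to 2020 in MRTFB dN dPY, 83 to 2225 and 50 to 1815 in MRTFB dN Y305A, and 244 to 2117 and 127 to 1750 in MRTFB dN Y305A/dPY than Puro vector. They ranged over 2 to 8 and 3 to 7 in MRTFB dN dPY and 354 to 452 and 865 to 976 in MRTFB dN Y305A than MRTFB dN, 137 to 1173 and 302 to 1250 in the Puro than the Hygro vector, and 0 to 2 and 0 to 3 in MRTFB dN Y305A/dPY than MRTFB dN Y305A. Positive and negative interactions ranged over 1 to 3 and 1 to 4, the overlap over 39 to 197, and the classes of Y305A only, both and neither over 714 to 1138, 3 to 14 and 682 to 2019. The MRTF/SRF median ranged over -0.65 to 0.55 in YAP 5SA, where both ends passed (adjusted p = 0.02 and 0.00043), 0.69 to 1.23 in MRTFB dN Y305A/dPY (not passing without Puro vector replicate 1) and -0.28 to 0.23 in MRTFB dN dPY minus MRTFB dN (passing without MRTFB dN dPY replicate 1), and the YAP/TEAD median over -0.021 to 0.304 in MRTFB dN Y305A/dPY and -0.199 to 0.006 in MRTFB dN dPY minus MRTFB dN.

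Single genes whose sign turned with 1 library left out ranged as follows. In YAP 5SA, PAFAH1B2,SIDT2,TAGLN ranged over -1.41 to 0.96 and VCL over -0.93 to 0.12. Between the vectors CTGF ranged over -1.23 to 0.60 and CYR61 over -1.87 to 0.15. Against the Puro vector PAFAH1B2,SIDT2,TAGLN ranged over -0.30 to 0.37 in MRTFB dN Y305A and -0.21 to 0.10 in MRTFB dN Y305A/dPY. Against MRTFB dN, PAFAH1B2,SIDT2,TAGLN ranged over -0.62 to 0.28 and AMOTL2 over -0.29 to 0.37 in MRTFB dN dPY, and AMOTL2 over -0.38 to 0.36 in MRTFB dN Y305A. In MRTFB dN Y305A/dPY minus MRTFB dN Y305A, ACTA2 ranged over -0.57 to 0.29 and PAFAH1B2,SIDT2,TAGLN over -0.43 to 0.25.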

Other observations

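The tests of Puro vector replicate 1, of the vector difference, of 1 library and of the PY deletion in the double mutant were chosen after the result was seen.

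Some groups differed between the vectors. Genes of the unfolded protein and integrated stress response rose in 5 of 18 in the Puro against the Hygro vector (6 adjusted over the list alone, median 0.80, camera adjusted p = 0.0013, but adjusted p = 0.26 with an estimated correlation), replication-dependent histone genes fell in 3 of 10 (5 adjusted over the list alone, median -1.63, camera adjusted p = 0.0013, adjusted p = 0.26 with an estimated correlation), and ribosomal protein genes fell in 3 of 29 (1 adjusted over the list alone, median -1.33, camera adjusted p = 1.3e-05, adjusted p = 0.65 with an estimated correlation). The histone genes also fell in 3 of 10 in YAP 5SA against the Hygro vector (4 adjusted over the list alone, median -1.61, camera adjusted p = 5.7e-05, but adjusted p = 0.12 with an estimated correlation). In MRTFB dN against the Puro vector 4 of 10 histone genes rose, also adjusted over the list alone (camera adjusted p = 0.044, but adjusted p = 0.52 with an estimated correlation). Basal and myoepithelial genes went both ways there, with 5 of 13 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.71), as did immediate early targets of TCF and SRF, with 5 of 16 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.71), and of 10 luminal genes 3 rose (3 adjusted over the list alone, with 1 lower, camera adjusted p = 0.22). Of 6 measured leukocyte markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.14). The keratin locus KRT6A,KRT6B,KRT6C fell 12.3-fold in the Puro against the Hygro vector (adjusted p = 0.0086).

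Many genes differed between MRTFB dN Y305A and the Puro vector, 3310 in all. Whether Puro vector replicate 1 alone was the source is open: 25.2% of them (835) were called in the same direction without it, with 1 Puro sample left. A difference between the vector controls stays open. Genes called without 1 MRTFB dN Y305A library were read in that library against the mean of the Hygro vector, each turned to its called direction. The median was 1.1 (lower quartile 0.45) for the 133 genes called without replicate 1 and 0.11 (lower quartile -0.16) for the 2548 called without replicate 2, so the 2 libraries do not decide it. The labels do not say which vector carried MRTFB, and a true response to MRTFB dN Y305A among these genes was not tested apart from it.

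Mitosis genes were lower in MRTFB dN dPY than in MRTFB dN. With each of the 4 libraries left out in turn the list median stayed below -0.5, a limit set after the result was seen. The direction thus did not rest on 1 library, but the size did vary. The median was -0.87 without MRTFB dN dPY replicate 1 and -1.72 without MRTFB dN dPY replicate 2. None of the 25 members lies in the empty part of MRTFB dN dPY replicate 1. The PY deletion itself may lower these genes: in the pair without SRF binding the list median was -1.02, with 25 of 25 members below 0 (p = 0.0064 with an estimated correlation, and adjusted p = 0.071 over lists). The members vary together (estimated correlation 0.751), so they are not 25 separate observations. Cell density, cell number and infection rate differ from culture to culture and were not tested. This is a hypothesis from the same data.

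Genes raised by YAP 5SA were asked whether they fall when MRTFB cannot bind YAP. With the mitosis and DNA replication lists removed, 501 such genes had a median of -0.04 in MRTFB dN dPY minus MRTFB dN, with 288 below 0 (camera p = 0.0072, and p = 0.034 with an estimated correlation), a very small shift. Their quartiles were -0.29 and 0.11, and the median of all genes was -0.01. Only members of those lists were removed, so other genes of cell division can remain among the 501. In MRTFB dN Y305A/dPY minus MRTFB dN Y305A the median was -0.02, with 257 below 0 (camera p = 0.16, and p = 0.27 with an estimated correlation), which decides nothing.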
